A study of Mus musculus with 12 samples.

How the data were processed

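RNA was measured in epithelial cells of the mouse circumvallate papilla, the large taste papilla at the back of the tongue, from adults of 11 to 12 weeks. The mice carried a Sox2 reporter with green fluorescent protein (GFP). Per the labels' protocols, the epithelium was freed with enzymes, dissociated into cells and sorted by GFP brightness into 4 bins, named Low, MedLow, HiMed and High. Cells without GFP were thrown away, so no GFP-negative cells were measured. Polyadenylated RNA was made into libraries with a NuGen Universal Plus kit and sequenced on a NovaSeq instrument. Each bin has 3 libraries, 12 in all, and each replicate pooled between 7 and 13 mice. The labels give no sequencing batch or sorting day.

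Per the submitters' processing notes, reads were quantified with Salmon 1.4.0, and DESeq2 1.28.1 and the mouse build mm39 are also named. What DESeq2 was used for, the annotation, and how transcripts were summed to genes are not given in the sources used here. The deposited estimated counts are Salmon's expected counts per gene symbol, unscaled, with 52670 symbols, and 8.24 to 13.0% of the values in a library were not whole numbers. The deposited TPM values sum to the same total in every library. A transcript named eGFP is among the symbols. The reference annotation at hand is of another build, so no coordinates are given.

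Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, which left 17432 genes. The 35238 symbols left out held 0.0339% of all counts. Libraries were scaled by TMM (trimmed mean of M values), and a quasi-likelihood model with 1 term per bin was fitted to all 12 libraries, so every comparison shares 1 estimate of the spread. The comparisons were High against Low, High against HiMed, HiMed against MedLow and MedLow against Low, plus a test of any difference among the 4 bins. The Benjamini-Hochberg method adjusted p over all genes tested, separately for each comparison, and a call needed an adjusted p below 0.05. A gene was counted as highest in a middle bin when the tests against both neighbouring bins called it higher there. The remaining bin was not part of that test, so such a gene can have a larger mean in it. CPM values, counts scaled to a common library total, were computed from the deposited counts with TMM scaling. A standard error of a log2 fold change is the value that the quasi-likelihood F statistic implies.

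In all, 28 lists with 345 gene symbols (taste cell types, progenitors, signalling pathways, cell cycle, keratinocytes, other cell types of the tongue, metabolism and stress) were fixed before the data were examined. Of these symbols, 344 were among the 52670 and 311 were tested. Lists were tested with camera from limma 3.58.1, which compares a list's genes with all others, at a preset correlation of 0.01 between genes and again with an estimated correlation. Adjustment of camera p was over the 28 lists, and for the gene families grouped by symbol over all families tried. Counts adjusted over the list alone use only the list's own genes.

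The genes named were chosen by a rule written before the data were examined. It takes Sox2, then up to 10 genes per direction and comparison with the largest fold change. Those had to be called, have bins whose libraries did not overlap, reach a mean of 10 CPM in the higher bin, and carry a symbol that is not a clone or predicted-gene name. It also takes up to 4 changed members of each list per comparison, other list members by value, the 10 leading genes of each middle bin, and Krt8, Krt5, Krt14, Krt13, Lgr5, Lgr6, Shh, Mki67, Trpm5, Entpd2, Car4, Ptch1 and Trp63. The reporter transcript and the gene families grouped by symbol lie outside that rule and were chosen after their values were seen.

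Totals per library ran from 25.7 M counts (Low replicate 2) to 55.6 M (HiMed replicate 3). The common biological coefficient of variation was 0.366. A gene with 0 counts in a bin is set against a floor of 3 counts over the bin's 3 libraries, which is 0.0284 CPM in Low, 0.0254 in MedLow, 0.0223 in HiMed and 0.0200 in High. Such intervals and floors cover counting error only. Libraries of the same bin differed by more than counting noise, with chi-square per degree of freedom between 27.5 and 92.4, so none is a copy of another.

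Replicates 1 to 3 occur in every bin. The series describes each replicate as a pool of mice sorted into the bins, and on that ground the numbers were taken to pair the libraries. The labels do not say outright that a number marks the same pool in every bin. Over 9927 genes, deviations from the bin mean correlated at 0.0386 to 0.375 in the 18 same-number pairs, 17 of them above 0.1, and at -0.218 to -0.00140 in the 36 other pairs. All 12 libraries correlated best with libraries of their own number. Deviations within a bin cancel out, so positive correlations in same-number pairs push those of the other pairs to negative values. The negative range is therefore no separate evidence of pairing. The fit without the replicate number as a block was fixed beforehand as the one reported.

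Alternatives fixed before the data were examined were edgeR's RLE (relative log expression) size factors, library size only, and no filter or a filter of at least 1 CPM in 3 libraries. Fixed as well were the Wald test of DESeq2 1.42.0 (likelihood ratio test for the 4 bins), limma voom on unrounded counts and the replicate block. The rest were a fit of only the 6 libraries compared, and limma on log2(TPM + 1) or log2(TPM + 0.1). In the TPM fits, genes needed a TPM of 1 in 3 libraries, or any value above 0. Each library was also left out in turn. The edgeR, voom, DESeq2, limma and camera steps were tested on simulated counts with known changes, while the other scalings and filters, the block and the 6-library fit were not. In simulated High against Low over 16729 genes, edgeR found 9 of 63 genes changed by 0.5 on the log2 scale, 31 of 65 changed by 1 and 40 of 65 changed by 2, with 3 false calls. For the HiMed peak, 68 of 100 simulated genes were found with 0 false calls. Over the 4 bins edgeR found 82 of 115 with 3 false calls, voom 80 with 4 false calls and DESeq2 89 with 54 false calls, and limma on log values found 83 of 101 with 8 false calls. Far fewer genes were changed in the simulations than differed in the data, and libraries were drawn without a shared replicate effect. The rates found therefore do not give the power of the comparisons reported.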

Results

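Gene expression was measured in circumvallate papilla epithelium sorted by the brightness of a Sox2 reporter. The 12 libraries form 4 bins of 3, Low, MedLow, HiMed and High, and every value with ± is a mean and SD over n = 3 libraries. Libraries averaged 35.8 M counts in Low, 40.6 M in MedLow, 44.5 M in HiMed and 48.2 M in High. Of 17432 genes tested, 7325 (42.0%) differed among the 4 bins in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, from which all adjusted p-values of single genes come. Of those 7325 genes, the mean rose from each bin to the next in 1479 (20.2%) and fell in 1576 (21.5%), where an order drawn at random gives 4.17% each. High held the largest mean for 2966 genes, Low for 2220, MedLow for 1237 and HiMed for 902. The leading principal component of the 1000 most variable genes held 53.9% of the variance and set the bins in order of brightness. The next component held 14.7%, with Low and High on one side and the middle bins on the other.

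Sox2, the transcription factor whose reporter was sorted, rose with brightness from 70.3 ± 6.17 CPM in Low to 98.0 ± 1.20 in MedLow, 171 ± 2.64 in HiMed and 373 ± 12.8 in High. Its log2 fold change of High over Low was 2.41 (SE 0.08, adjusted p = 8.5e-12). The step from MedLow to HiMed was 0.81 (SE 0.07, adjusted p = 3.8e-06) and that from HiMed to High 1.12 (SE 0.07, adjusted p = 1.4e-07). From Low to MedLow, Sox2 rose by 0.48 (SE 0.07, adjusted p = 6.7e-04). The eGFP transcript, chosen after its values were seen, rose alongside from 84.2 ± 5.96 to 538 ± 15.7 CPM, with a log2 fold change of High over Low of 2.68. There were 1.20 ± 0.129 eGFP counts per Sox2 count in Low, 1.48 ± 0.0951 in MedLow, 1.44 ± 0.123 in HiMed and 1.45 ± 0.0554 in High.

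**Figure D1:**
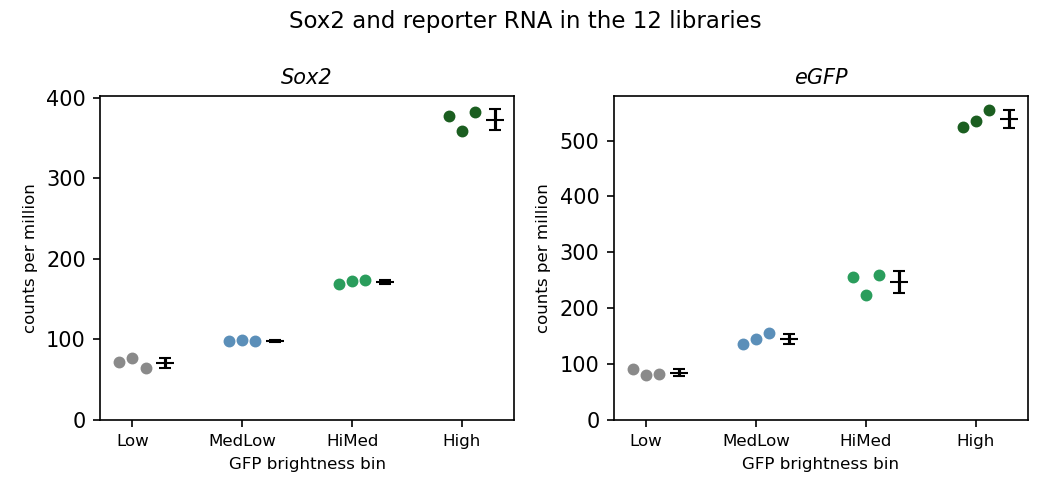
Sox2 and eGFP transcripts in CPM (vertical axis) for each library, by GFP bin (horizontal axis), with the mean and SD over 3 libraries. Both rise at every step, Sox2 from 70.3 CPM in Low to 373 CPM in High.

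High against Low asked how cells with the most Sox2 differ from those with the least. Taste bud keratins and the taste placode signal Shh were far higher in High, and the basal keratins Krt14 and Krt15 far lower. Shh, a ligand made by taste precursor cells, had 0.140 ± 0.121 CPM in Low and 128 ± 6.48 in High (log2 fold change 9.63, SE 0.92, adjusted p = 3.4e-05). Krt8, a keratin of differentiated taste cells, rose from 259 ± 46.1 to 1085 ± 356 CPM (2.06, SE 0.28, adjusted p = 2.5e-04). Krt14 fell by 4.21 on the log2 scale, from 7397 ± 321 to 401 ± 68.3 CPM (SE 0.14, adjusted p = 1.2e-11), and Krt15 fell by 7.88, from 6226 ± 475 to 26.4 ± 8.26 CPM (SE 0.35, adjusted p = 4.8e-08). In all, 7182 genes differed, 3489 higher in High and 3693 lower, of which 1767 and 1510 differed by at least 2-fold and 536 and 622 by at least 8-fold. The balance turned under other scalings and filters, to 3976 higher and 3149 lower with library size only, 4204 and 1993 with TPM + 1, 4125 and 1995 with TPM + 0.1, 3980 and 2012 with TPM unfiltered and 3591 and 3442 with a filter of 1 CPM in 3 libraries. It was 3164 and 3154 without Low replicate 2. The 3 High libraries lay wholly above or below the 3 Low libraries for 52.4% of genes tested, where chance gives 10%.

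Among the largest differences between High and Low were several genes with 0 counts on the other side. The protocadherin Pcdh15 was at least 1772-fold higher in High (50.9 ± 21.8 CPM), the polysialic acid enzyme St8sia2 at least 831-fold and the growth factor Fgf3 at least 640-fold. Serpina1e had 199 ± 111 CPM in High and 0.0770 ± 0.0764 in Low. In the other direction, the homeobox gene Irx4 was at least 2736-fold lower in High (55.1 ± 1.46 CPM in Low), and the metallothionein Mt3 at least 1417-fold. Its relative Mt4 fell from 538 ± 62.1 to 0.979 ± 0.593 CPM. Each of these 7 genes was called, with edgeR adjusted p between 5.0e-11 for Irx4 and 4.2e-04 for St8sia2.

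Markers of the taste cell types went apart between High and Low. Type I cells are the glia-like cells of the bud. Of their 4 markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone). The ecto-ATPase Entpd2 rose from 19.9 ± 3.68 to 205 ± 64.1 CPM (3.37, SE 0.21, adjusted p = 1.3e-07), the potassium channel Kcnj1 rose by 9.74 and the oxytocin receptor Oxtr by 7.64. The glutamate transporter Slc1a3 fell from 49.7 ± 3.89 to 0.0725 ± 0.126 CPM (-9.24). The list's median was 5.51 (camera adjusted p = 0.0213, and adjusted p = 0.368 with an estimated correlation). Without HiMed replicate 1 the camera test of this list pointed down, at adjusted p = 0.70. Type II cells carry the sweet, umami and bitter receptors, and of 15 markers 8 fell, 1 rose and 6 were not called (9 and 1 adjusted over the list alone). Rgs21 fell from 25.5 ± 11.2 to 2.38 ± 0.442 CPM (-3.42, adjusted p = 1.2e-04), the sweet receptor subunit Tas1r2 by 3.29 and Tas1r3 by 2.35, and the bitter receptor Tas2r105 was at least 189-fold lower. The channel Trpm5 fell from 62.9 ± 24.9 to 18.6 ± 4.53 CPM (-1.76, adjusted p = 0.0112), though at adjusted p = 0.0517 without High replicate 3. Pou2f3, which specifies type II cells, had 20.6 ± 3.66 and 23.6 ± 2.09 CPM and was not called (0.20, adjusted p = 0.354). The type II list's median was -1.56 (camera adjusted p = 0.0128, and adjusted p = 0.781 with an estimated correlation). Of 11 tested markers of the sour-sensing type III cells, 5 fell and 1 rose (6 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.225). The proton channel Otop1 rose from 7.28 ± 3.03 to 122 ± 49.2 CPM (4.05, adjusted p = 4.6e-05), while the partner channel gene Pkd1l3 fell from 152 ± 37.8 to 19.8 ± 9.81 (-2.94, adjusted p = 2.1e-04) and the synaptic gene Snap25 by 2.29. Car4, another type III marker, had 3.70 ± 0.527 and 1.41 ± 0.376 CPM and was not called (-1.39, adjusted p = 0.243, and 0.0442 with TPM + 1).

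Most general taste bud genes and taste lineage factors rose. Of 8 taste bud keratins and related genes, 7 rose and 0 fell (7 adjusted over the list alone), with Krt19 at 3.12, Krt7 at 3.03, Kcnq1 at 2.96 and Cldn7 at 2.92. Cldn8 alone was not called (0.20, adjusted p = 0.254, and 0.0433 with TPM + 1), and the list's median was 2.49 (camera adjusted p = 1.7e-06, and adjusted p = 0.368 with an estimated correlation). Of 11 tested lineage factors, Shh counted among them, 7 rose, 2 fell and 2 were not called (7 and 2 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 2.2e-04, and adjusted p = 0.368 with an estimated correlation). Prox1 rose from 11.6 ± 3.77 to 143 ± 36.2 CPM (3.60), Hes6 from 34.4 ± 2.68 to 384 ± 9.05 (3.48, SE 0.12, adjusted p = 1.2e-11) and Foxa2 by 2.72.

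Stem and progenitor markers split. Of 11, 3 rose and 6 fell (3 and 6 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 0.0131, and adjusted p = 0.369 with an estimated correlation). The R-spondin receptors Lgr5 and Lgr6 rose, Lgr5 from 9.9998 ± 2.75 to 175 ± 18.8 CPM (4.12, SE 0.25, adjusted p = 3.4e-07) and Lgr6 from 67.7 ± 9.91 to 661 ± 18.9 (3.29, SE 0.16, adjusted p = 5.8e-09). Krt5 fell from 13833 ± 128 to 3959 ± 911 CPM (-1.80, adjusted p = 3.4e-08), and the epidermal master regulator Trp63 from 869 ± 9.25 to 454 ± 114 (-0.94, adjusted p = 6.1e-05). Most genes that anchor basal cells fell with them. Of 11 hemidesmosome and basement membrane genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), led by Dst (-2.35, SE 0.08, adjusted p = 2.1e-11), Col17a1 (-1.85) and Itga3 (-1.40). Their median was -0.81 (camera adjusted p = 1.2e-07, and adjusted p = 0.368 with an estimated correlation). Most G2 and M phase genes were lower too. Of 16 G2 and M phase genes 11 fell and 0 rose (13 and 0 adjusted over the list alone), among them Mki67 from 528 ± 62.0 to 192 ± 29.8 CPM (-1.46, adjusted p = 5.7e-08) and Ccnb2 at -1.44. The G2 and M phase median was -0.88 (camera adjusted p = 4.9e-05, and adjusted p = 0.506 with an estimated correlation). Of 15 S phase genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), including Cdt1 (-1.09), and the list was not called (adjusted p = 0.170, and 0.0311 with no filter on low counts).

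Some signalling genes differed in each pathway, as did 7182 of all 17432 genes tested. Of the pathway lists only that of Hedgehog was called, with the preset correlation. Of 8 Hedgehog genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 0.00902, and adjusted p = 0.441 with an estimated correlation). Besides Shh, the target genes Ptch1 (3.05, SE 0.17, adjusted p = 2.0e-08) and Gli1 (2.11) rose. Of 16 Wnt genes, 10 rose and 5 fell (10 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.125, 0.0349 with no filter on low counts and 0.03685 without MedLow replicate 1). The secreted inhibitors Wif1 (7.29 ± 2.44 to 255 ± 64.6 CPM, 5.11) and Notum (28.1 ± 3.77 to 489 ± 83.0 CPM, 4.12) rose with Nkd1 (4.91), while the ligand Wnt10b was at least 228-fold lower in High. Of 13 Notch genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone). The effectors Heyl (6.91) and Hey1 (4.25) rose, the ligands Dll1 (-2.77) and Jag2 (-2.20) fell, and Hes1 had 477 ± 107 and 468 ± 85.6 CPM and was not called (-0.03, adjusted p = 0.936). Of 16 BMP and TGF-beta genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone), with Bmpr1b (4.67) and Fst (1.84) up and Tgfbi (-4.05) and Id2 (-1.15) down. The Notch list (adjusted p = 0.818; median -0.02, mean 0.69, test down) and the BMP list (adjusted p = 0.667) were not called.

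Keratinocyte programs of the papilla wall moved both ways. The suprabasal keratin Krt13 fell from 5692 ± 498 to 683 ± 195 CPM (-3.06, adjusted p = 2.1e-04), with Dsg1a (-4.94) and Krt1 (-4.61), while Mal rose by 5.86. Of 19 suprabasal genes 8 rose and 6 fell (8 and 6 adjusted over the list alone), with a median of 0.21, a mean of -0.28 and a test pointing up (adjusted p = 0.758). Of 19 cornified envelope genes the counts were again 8 and 6 (8 and 6 adjusted over the list alone), with the filiform papilla keratins Krt36 (-8.10), Krt84 (-7.52) and Krt76 (-7.36) and filaggrin, Flg (-6.74), lowest. That list had a median of 0.02, a mean of -0.84 and a test pointing up (adjusted p = 0.667). Of 13 glycolysis genes 11 fell and 0 rose (11 and 0 adjusted over the list alone), including Pfkp (-1.51) and the glucose transporter Slc2a1 (-1.33). The glycolysis median was -0.64 (camera adjusted p = 2.5e-04, and adjusted p = 0.441 with an estimated correlation). Of 17 immediate early genes 10 fell and 0 rose (10 and 0 adjusted over the list alone), among them Socs3 (-1.90) and Fosb (-1.09). The median of immediate early genes was -0.41 (camera adjusted p = 0.0131, adjusted p = 0.619 with an estimated correlation, and adjusted p = 0.0566 without High replicate 2).

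Markers of other tongue cell types were measured beside these. The fibroblast gene Dcn fell from 608 ± 20.8 CPM in Low to 6.95 ± 4.20 in High (-6.45, adjusted p = 1.4e-05), and the Schwann cell factor Sox10 from 6.97 ± 1.99 to 0.0332 ± 0.0575 (-7.59, adjusted p = 4.2e-05), together with the basal keratins. Dcn was the only fibroblast marker called lower, while 3 of the 6 tested rose (list median 1.38, mean 0.53). Col1a2, Col3a1, Lum, Pdgfrb and Postn did not pass the count filter. Among von Ebner gland genes, Muc5b fell by 8.56 and Dmbt1 from 900 ± 338 to 8.67 ± 11.7 CPM (-6.68, adjusted p = 0.00297), while the water channel Aqp5 rose by 3.84. The gland product Bpifb1 varied between libraries of Low (92.8, 596 and 429 CPM) and stood at 50.8 CPM in High replicate 2, where Amy1 also reached 19.2 CPM. Counts of higher and lower members were 3 and 3 of 14 gland genes (adjusted p = 0.985; median -1.65, mean -1.53, test up), 1 and 3 of 8 leukocyte genes (0.667), 3 and 1 of 6 fibroblast genes (0.800), 1 and 0 of 5 endothelial genes (0.972; median -0.08, mean 0.91) and 0 and 4 of 10 neuron and Schwann genes (0.220). They were 0 and 1 of 4 skeletal muscle genes (0.818; median 0.01, mean -1.69), 0 and 0 of 3 melanocyte genes (0.818) and 0 and 1 of 4 erythroid genes (0.667). Interferon genes gave 1 and 4 of 14 (0.667), mitochondrial genes 0 and 4 of 13 (0.225) and excitability genes 5 and 7 of 13 (0.667; median -0.62, mean 0.36, test down). In each of these 11 lists the counts adjusted over the list alone were the same, and no list was called.

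**Figure D2:**
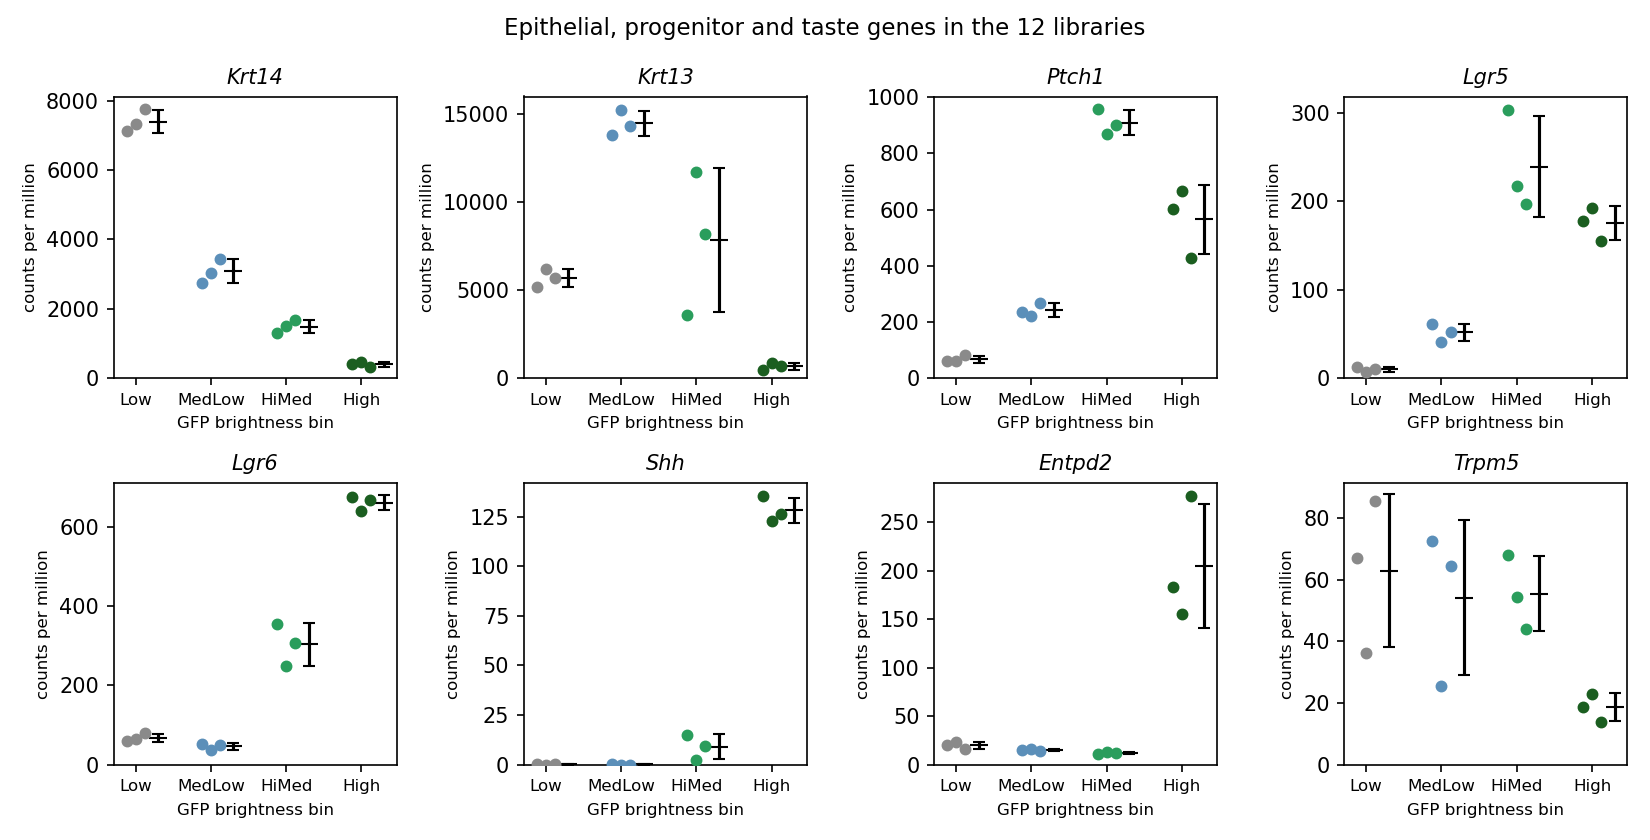
CPM (vertical axis, linear scale) of Krt14, Krt13, Ptch1, Lgr5, Lgr6, Shh, Entpd2 and Trpm5 in each of the 12 libraries by GFP bin (horizontal axis), with the mean and SD over 3 libraries. Krt14 falls at each step, Ptch1 and Lgr5 have their largest means in HiMed, and Entpd2 stands at 205 CPM in High against 12.2 CPM in HiMed.

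High against HiMed asked what sets the brightest cells apart from those just below. Most type I and general taste bud genes rose in High, and several genes of type II cells and suprabasal keratinocytes fell. Entpd2 rose from 12.2 ± 1.23 to 205 ± 64.1 CPM (4.07, SE 0.22, adjusted p = 3.0e-07), and Otop1 from 10.4 ± 2.68 to 122 ± 49.2 (3.54, SE 0.42, adjusted p = 3.0e-04). Krt13 fell from 7851 ± 4092 to 683 ± 195 CPM (-3.52, adjusted p = 3.0e-04) and Krt4 from 7542 ± 3598 to 762 ± 155 (-3.31, adjusted p = 1.7e-04). In all, 3886 genes differed, 1846 higher in High and 2040 lower. More were higher than lower with library size only (2056 and 1783), voom (2186 and 2085), TPM + 1 (2009 and 1062), TPM + 0.1 (1887 and 1087), TPM unfiltered (1746 and 860) and the fit of the 6 libraries alone (1568 and 1294). The libraries of the bins did not overlap for 35.3% of genes, against 10% by chance. Genes named by size included the phosphatase Ptpro (0.0790 ± 0.121 to 14.7 ± 3.23 CPM, 7.64), Igf1 (5.92), Fgf20 (5.00) and the potassium channel Kcnj5 (3.84 ± 1.75 to 92.7 ± 33.2 CPM, 4.58) among those higher. Among those lower they included the protease inhibitors Serpinb3a (-8.33) and Serpinb12 (-6.24), the metallothionein Mt4 (-8.10) and Krt1 (-5.98).

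Between HiMed and High, 3 of 4 type I markers rose and 1 fell (3 and 1 adjusted over the list alone; median 3.93, camera adjusted p = 9.8e-05). This list's adjusted p was 0.0676 with an estimated correlation and 0.234 without HiMed replicate 1. The 1 that fell, Slc1a3 (-3.84, adjusted p = 0.04999), lost its call without each library but HiMed replicate 1 (adjusted p = 0.0568 to 0.152), with the replicate block (0.0866), with library size only (0.0503) and with TPM + 1 (0.174). Of 15 type II markers 10 fell and 0 rose (11 and 0 adjusted over the list alone), with Rgs21 at -3.23 (22.3 ± 6.48 to 2.38 ± 0.442 CPM), Tas1r3 at -2.74 and Tas1r2 at -2.46. Their median was -1.90 (camera adjusted p = 2.4e-05, and adjusted p = 0.496 with an estimated correlation). Pou2f3 (-0.03, adjusted p = 0.936) and Fxyd6 (0.49, adjusted p = 0.334) were not called. Of 8 taste bud keratins and related genes 7 rose (7 adjusted over the list alone), led by Krt7 (2.51), Kcnq1 (2.17) and Krt8 (2.09, adjusted p = 6.6e-04). The median of these 8 was 1.65 (camera adjusted p = 1.0e-08, and adjusted p = 0.200 with an estimated correlation). Of 11 lineage factors 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Shh at 3.83 (adjusted p = 0.00214), Prox1 at 2.57 and Hes6 at 0.93. The lineage factor median was 0.25 (camera adjusted p = 0.0259, and adjusted p = 0.528 with an estimated correlation). The adjusted p of the lineage factors was 0.0585 without HiMed replicate 1, 0.0569 without High replicate 1 and 0.0548 without High replicate 3. Of 11 type III markers 2 rose and 4 fell (2 and 4 adjusted over the list alone), among them Pkd1l3 (-1.98) and Snap25 (-1.76), and the list was not called (adjusted p = 0.263, and 0.0486 without High replicate 3).

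Several basal genes fell again from HiMed to High. Of 11 stem and progenitor markers 6 fell and 1, Lgr6, rose (6 and 1 adjusted over the list alone; median -0.45, camera adjusted p = 4.4e-05, and adjusted p = 0.132 with an estimated correlation). Krt15 fell by 4.64, Krt14 by 1.90 and Trp63 from 920 ± 30.8 to 454 ± 114 CPM (-1.02, adjusted p = 1.1e-04). Lgr6 rose from 304 ± 53.9 to 661 ± 18.9 CPM (1.12, adjusted p = 1.5e-04), and Lgr5 had 239 ± 56.7 and 175 ± 18.8 CPM with no call (-0.45, adjusted p = 0.181). Of 11 hemidesmosome genes 5 fell and 2 rose (6 and 2 adjusted over the list alone; median -0.30, camera adjusted p = 0.00590, and adjusted p = 0.496 with an estimated correlation), among them Dst (-1.10) and Col17a1 (-1.04). Of 16 G2 and M phase genes 9 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.56, camera adjusted p = 2.4e-05, and adjusted p = 0.496 with an estimated correlation), with Mki67 at -0.81 (adjusted p = 8.1e-05). Of 15 S phase genes 4 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.40, camera adjusted p = 0.00717, and adjusted p = 0.528 with an estimated correlation), with Mcm4 at -0.78.

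Hedgehog target genes were lower in High than in HiMed, although Shh itself was higher. Ptch1 fell from 909 ± 44.0 to 566 ± 123 CPM (-0.68, SE 0.15, adjusted p = 0.00650), Gli1 by 0.99 (adjusted p = 0.00122) and Gli2 by 1.04 (adjusted p = 6.2e-04). Of the 8 Hedgehog genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.82, camera adjusted p = 0.00362). The Hedgehog adjusted p was 0.484 with an estimated correlation and 0.0594 without HiMed replicate 2. Of 16 Wnt genes 8 rose and 5 fell (8 and 5 adjusted over the list alone; median 0.39, camera adjusted p = 0.0259), with Notum (3.39) and Nkd1 (3.04) up and the ligand Wnt10a down (49.5 ± 4.72 to 8.16 ± 2.21 CPM, -2.60, adjusted p = 9.7e-08). The Wnt list's adjusted p was 0.238 with an estimated correlation, 0.0723 with the replicate block and 0.0519 without HiMed replicate 3. Of 16 BMP and TGF-beta genes 6 rose and 1 fell (6 and 3 adjusted over the list alone; median 0.06, camera adjusted p = 0.0422), with Tgfb2 (2.26) and Bmp2 (1.81) up and Tgfbi (-1.96) down. The BMP list's adjusted p was 0.484 with an estimated correlation, 0.1004 with the replicate block, 0.102 without HiMed replicate 2 and 0.0949 without High replicate 1. Of 13 Notch genes 3 rose and 5 fell (5 and 5 adjusted over the list alone), including Notch1 (-0.89), Dll1 (-1.11) and Jag2 (-1.28), and the list was not called (adjusted p = 0.484; median 0.20, mean 0.32, test down).

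Of 19 suprabasal genes 8 fell and 2 rose from HiMed to High (9 and 3 adjusted over the list alone; median -0.55, camera adjusted p = 3.8e-04, and adjusted p = 0.528 with an estimated correlation). HiMed replicate 1 had 3585 CPM of Krt13, against 11744 and 8225 CPM in the other HiMed libraries. Of 13 glycolysis genes 6 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.28, camera adjusted p = 0.00530, and adjusted p = 0.528 with an estimated correlation), with Pfkp at -0.68 and Slc2a1 at -0.60. Of 13 mitochondrial genes 4 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.27, camera adjusted p = 0.00777), with mt-Co2 at -1.64 and mt-Atp6 at -0.77. The mitochondrial list's adjusted p was 0.496 with an estimated correlation and 0.0585 without HiMed replicate 1. The other lists were not called. Counts of higher and lower members were 1 and 5 of 19 cornified envelope genes (adjusted p = 0.3625), 3 and 2 of 14 gland genes (0.804; 3 and 3 adjusted over the list alone), 1 and 1 of 8 leukocyte genes (0.804; 1 and 2), 1 and 2 of 6 fibroblast genes (0.408) and 0 and 1 of 5 endothelial genes (0.755; median -0.34, mean 0.90). They were 0 and 3 of 17 immediate early genes (0.137; 0 and 2 adjusted over the list alone; adjusted p = 0.0265 with no filter on low counts, 0.0273 without HiMed replicate 2, 0.0481 without High replicate 1 and 0.0485 without High replicate 3), 1 and 2 of 14 interferon genes (0.873; 1 and 3; median 0.12, mean -0.24, test down) and 4 and 5 of 13 excitability genes (0.801). No neuron, skeletal muscle, melanocyte or erythroid gene was called (adjusted p = 0.674, 0.873, 0.643 and 0.829, the muscle median 0.24 and mean -0.06). Where no other count is given, the list alone gave the same. Among the members the gland genes Aqp5 (4.07) and Ano1 (1.86) rose and Wfdc2 (-2.37) fell, Dcn fell by 2.30, and the cornified envelope gene Sprr1b fell by 4.19 (adjusted p = 0.00117).

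HiMed against MedLow asked what differs between the middle bins. Shh, Hes6 and the Lgr5 and Lgr6 receptors rose, and Krt15 and Krt14 fell. Shh rose from 0.0686 ± 0.119 to 8.98 ± 6.41 CPM (7.00, SE 1.05, adjusted p = 0.00259), with 15.1, 2.30 and 9.56 CPM in the 3 HiMed libraries. Hes6 rose from 42.4 ± 6.21 to 201.3 ± 22.6 CPM (2.25, SE 0.11, adjusted p = 1.9e-08), Lgr6 from 45.9 ± 7.97 to 304 ± 53.9 (2.73, SE 0.16, adjusted p = 4.6e-07) and Lgr5 from 51.8 ± 9.98 to 239 ± 56.7 (2.21, adjusted p = 1.3e-04). Krt15 fell from 4885 ± 462 to 659 ± 243 CPM (-2.89, SE 0.28, adjusted p = 1.0e-04), and Krt14 from 3084 ± 344 to 1492 ± 190 (-1.05, adjusted p = 5.6e-05). In all, 2377 genes differed, 1278 higher in HiMed and 1099 lower. With voom 1172 were higher and 1226 lower, and the count was 1402 without MedLow replicate 2 and 1196 with TPM unfiltered. The libraries did not overlap for 32.8% of genes, against 10% by chance. The fibrillin Fbn2 (1.53 ± 0.0604 to 38.3 ± 9.59 CPM, 4.64), carbonic anhydrase Car2 (4.13), the protease inhibitor A2m (55.2 ± 31.3 to 845 ± 224 CPM, 3.94) and the peptidase Mme (3.74) were among the genes named by size as higher. The hair follicle protein trichohyalin, Tchh (1306 ± 955 to 26.4 ± 3.37 CPM, -5.63), Irx4 (-5.26) and the imprinted genes Peg3 (-5.06) and H19 (-3.33) were among those named as lower.

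Of 11 lineage factors 8 rose and 1 fell between MedLow and HiMed (9 and 1 adjusted over the list alone; median 1.04, camera adjusted p = 2.8e-10, and adjusted p = 0.101 with an estimated correlation). Besides Shh and Hes6, Foxa2 rose by 1.63. Of 8 taste bud keratins and related genes 6 rose and 0 fell (7 and 0 adjusted over the list alone; median 1.03, camera adjusted p = 1.2e-05, and adjusted p = 0.320 with an estimated correlation), with Cldn7 at 1.65 and Krt18 at 1.17. Kcnj1 (5.12) rose and Slc1a3 (-4.13) fell among 4 type I markers (2 up, 1 down, and the same adjusted over the list alone; adjusted p = 0.490), and Entpd2 was not called (-0.29, adjusted p = 0.428). Of 15 type II markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.288), and of 11 type III markers 1 rose (1 adjusted over the list alone; adjusted p = 0.146, 0.0446 with the replicate block, 0.0465 with no filter on low counts and 0.0295 without MedLow replicate 3). Rgs21 had 23.03 ± 9.93 and 22.3 ± 6.48 CPM (-0.05, adjusted p = 0.971).

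Of 16 Wnt genes 7 rose and 4 fell from MedLow to HiMed (7 and 4 adjusted over the list alone; median 0.17, camera adjusted p = 2.8e-06, and adjusted p = 0.0650 with an estimated correlation), with Wif1 at 3.75 (23.97 ± 4.48 to 323 ± 71.0 CPM) and Notum at 3.41 (4.36 ± 1.18 to 46.4 ± 11.3 CPM). Of 8 Hedgehog genes 4 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.78, camera adjusted p = 2.0e-04, and adjusted p = 0.320 with an estimated correlation), and Ptch1 rose from 243 ± 23.3 to 909 ± 44.0 CPM (1.90, SE 0.16, adjusted p = 9.4e-06). Of 16 BMP genes 5 rose and 2 fell (6 and 3 adjusted over the list alone; median 0.26, camera adjusted p = 0.0322), with Fst (1.91) and Bmpr1b (1.59) up and Tgfbi (-1.32) down. The BMP list's adjusted p was 0.320 with an estimated correlation, 0.0605 without MedLow replicate 3, 0.0507 without HiMed replicate 1, 0.0749 without High replicate 2 and 0.105 without High replicate 3. Of 13 Notch genes 2 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.708; median -0.10, mean 0.37), namely Heyl (2.69), Hey1 (2.38), Dll1 (-1.16) and Notch1 (-0.66).

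Most G2 and M phase genes fell at this step. Of 16 G2 and M phase genes 14 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.73, camera adjusted p = 8.4e-11, and adjusted p = 0.320 with an estimated correlation), with Cenpe at -0.85 (adjusted p = 4.7e-05) and Ccnb1 at -0.87, and Mki67 fell from 553 ± 42.2 to 337 ± 9.85 CPM (-0.72, adjusted p = 3.9e-04). Of 15 S phase genes none was called, over all genes or adjusted over the list alone (list adjusted p = 0.708). Of 13 glycolysis genes 5 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.28, camera adjusted p = 3.0e-04, and adjusted p = 0.512 with an estimated correlation), with Pfkp at -0.81 and Slc2a1 at -0.76. Stem and progenitor markers split 3 up and 5 down of 11 (3 and 5 adjusted over the list alone; adjusted p = 0.761; median -0.19, mean 0.02, test up), and Trp63 had 914 ± 30.1 and 920 ± 30.8 CPM with no call (0.01, adjusted p = 0.983). Dst fell by 0.83 (adjusted p = 8.0e-06), 1 of 2 hemidesmosome genes called of 11 (0 up and 2 down adjusted over the list alone; adjusted p = 0.146, and 0.03625 without HiMed replicate 1). Among suprabasal genes the stress keratins parted, with Krt17 up from 6148 ± 952 to 16194 ± 525 CPM (adjusted p = 9.5e-06) and Krt16 down (-1.49, adjusted p = 0.00600), and the list, with 3 up and 1 down of 19 (3 and 1 adjusted over the list alone), was not called (adjusted p = 0.868; median -0.04, mean -0.05, test up).

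The remaining lists were not called between MedLow and HiMed. Counts of higher and lower members were 2 and 1 of 19 cornified envelope genes (adjusted p = 0.865; 3 and 3 adjusted over the list alone; median 0.07, mean -0.27, test up), 3 and 0 of 14 gland genes (0.568; median 0.13, mean -0.53, test up), 2 and 1 of 6 fibroblast genes (0.143, and 0.0219 without Low replicate 3) and 1 and 0 of 5 endothelial genes (0.316). They were 0 and 3 of 10 neuron and Schwann genes (0.434; 1 and 3 adjusted over the list alone; median 0.08, mean -0.22), among them Mbp (-0.71, adjusted p = 3.9e-04), and 6 and 3 of 13 excitability genes (0.578; 6 and 4). Immediate early genes gave 0 and 2 of 17 (0.137, 0.0447 without MedLow replicate 3 and 0.0473 without HiMed replicate 1), with Socs3 at -0.88, and interferon genes 0 and 1 of 14 (0.635; 0 and 0 adjusted over the list alone; median 0.02, mean -0.29). No leukocyte, skeletal muscle, melanocyte, erythroid or mitochondrial gene was called (adjusted p = 0.578, 0.865, 0.435, 0.829 and 0.621, the muscle median -0.28 and mean 0.06). Where no other count is given, the list alone gave the same. The fibrillin gene Fbn1 rose by 2.35 (adjusted p = 5.8e-04) among the fibroblast markers.

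MedLow against Low compared the dimmest bins. The Hedgehog targets Ptch1 and Gli1 and several suprabasal genes rose, and most anchoring genes and several Wnt and BMP genes fell. Ptch1 rose from 68.5 ± 12.3 to 243 ± 23.3 CPM (1.82, SE 0.16, adjusted p = 2.0e-05) and Gli1 from 32.6 ± 1.01 to 166 ± 12.1 (2.35, SE 0.18, adjusted p = 9.8e-06). Shh had 17 counts over the Low libraries and 8 over the MedLow libraries and was not called (-1.20, adjusted p = 0.888). Krt4 rose from 1291 ± 140 to 9474 ± 806 CPM (2.88, SE 0.35, adjusted p = 0.00107) and Lgr5 from 9.9998 ± 2.75 to 51.8 ± 9.98 (2.36, SE 0.24, adjusted p = 1.8e-04). Krt14 fell from 7397 ± 321 to 3084 ± 344 CPM (-1.26, SE 0.13, adjusted p = 1.8e-05). In all, 1127 genes differed, 691 higher in MedLow and 436 lower. The count was 730 without Low replicate 1, 718 without Low replicate 3, 702 without MedLow replicate 1 and 669 without MedLow replicate 3. It was 699 with TPM + 1, 647 with TPM + 0.1, 564 with TPM unfiltered and 1806 in a fit of the 6 libraries alone. The libraries did not overlap for 27.4% of genes, against 10% by chance. The GABA transporter Slc6a11 (0.778 ± 0.204 to 27.5 ± 5.14 CPM, 5.13), the cytochrome Cyp3a13 (3.57) and Krt75 (24.2 ± 5.58 to 266 ± 52.1 CPM, 3.46) were among the genes named by size as higher. The clotting factor F5 (25.3 ± 14.7 to 0.486 ± 0.282 CPM, -5.70), Lhx6 (-3.68) and Gp2 (-3.58) were among those named as lower.

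Hedgehog genes gave 4 up and 0 down of 8 between Low and MedLow (4 and 0 adjusted over the list alone; median 0.40, camera adjusted p = 4.1e-12, and adjusted p = 0.0348 with an estimated correlation). Of 16 Wnt genes 8 fell and 3 rose (10 and 3 adjusted over the list alone; median -0.54, camera adjusted p = 9.2e-07, and adjusted p = 0.0348 with an estimated correlation), with Notum down from 28.1 ± 3.77 to 4.36 ± 1.18 CPM (-2.68, adjusted p = 8.9e-05), Lef1 down (-1.91) and Wif1 up (1.69). Of 16 BMP and TGF-beta genes 4 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.34, camera adjusted p = 1.7e-06, and adjusted p = 0.0348 with an estimated correlation), with Tgfb2 at -2.70, Fst at -0.92, Id2 at -0.90 and Bmpr1b at 3.09. Of 11 hemidesmosome genes 9 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.45, camera adjusted p = 4.1e-12, and adjusted p = 0.0348 with an estimated correlation), among them Lamb3 (-0.56), Col7a1 (-0.59) and Plec (-0.53). Neuron and Schwann genes gave 0 up and 2 down of 10 (0 and 3 adjusted over the list alone; median -1.17, camera adjusted p = 0.00148, and adjusted p = 0.0348 with an estimated correlation). Sox10 fell by 4.21 (adjusted p = 0.00763, and 0.0698 without Low replicate 3). These 5 lists were called with both correlations. Gland products stood higher in Low beside them: Bpifb1 had 92.8, 596 and 429 CPM in the Low libraries against 0.129, 3.87 and 0.105 in MedLow, and Amy1 9.35, 135 and 58.6 against 0.411, 0.194 and 0.421, neither of them called (adjusted p = 0.0844 and 0.0597).

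Of 19 suprabasal genes 7 rose and 0 fell from Low to MedLow (12 and 0 adjusted over the list alone; median 0.81, camera adjusted p = 4.1e-12, and adjusted p = 0.227 with an estimated correlation), with Krtdap at 1.86 (177 ± 25.9 to 644 ± 105 CPM). Krt13 had 5692 ± 498 and 14483 ± 726 CPM and was not called (1.35, adjusted p = 0.0749), but passed with DESeq2 (adjusted p = 0.0026), with the replicate block (0.0296), with TPM + 1 (0.0434) and without HiMed replicate 1 (0.00142) or 2 (0.0365). Krt8, at 259 ± 46.1 and 124 ± 37.8 CPM, was not called either (-1.06, adjusted p = 0.0549), and passed with DESeq2 (adjusted p = 0.00364), with the block (9.1e-04) and with TPM + 1 (0.0276). It also passed without MedLow replicate 3 (0.0446), High replicate 2 (0.0370) or High replicate 3 (0.0343). Of 19 cornified envelope genes 3 rose and 1 fell (6 and 2 adjusted over the list alone; median 1.17, camera adjusted p = 0.00318, and adjusted p = 0.558 with an estimated correlation).

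Of 16 G2 and M phase genes 2 rose and 0 fell from Low to MedLow (7 and 0 adjusted over the list alone; median 0.46, camera adjusted p = 1.3e-05, and adjusted p = 0.478 with an estimated correlation), and Mki67 was not called (0.07, adjusted p = 0.879). Of 11 type III markers 2 fell and 0 rose (2 and 0 adjusted over the list alone; median -0.91, camera adjusted p = 2.8e-04, and adjusted p = 0.337 with an estimated correlation). None of 8 leukocyte genes was called, over all genes or adjusted over the list alone, while their list was (median -1.97, camera adjusted p = 0.0179, and adjusted p = 0.105 with an estimated correlation).

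The other lists were not called between Low and MedLow. Counts of higher and lower members, with those adjusted over the list alone in brackets, were 0 and 1 of 15 type II markers (0 and 2; adjusted p = 0.0698), 0 and 1 of 8 taste bud keratins (0 and 2; 0.0741), 1 and 4 of 11 stem markers (2 and 5; 0.0776) and 1 and 2 of 11 lineage factors (2 and 2; 0.356). Gland genes gave 1 and 2 of 14 (1 and 5; 0.0698), Notch genes 3 and 1 of 13 (4 and 4; 0.6495; median -0.02, mean -0.01, test up), fibroblast genes 1 and 1 of 6 (1 and 2; 0.729), immediate early genes 0 and 2 of 17 (0 and 2; 0.169) and interferon genes 0 and 1 of 14 (0 and 1; 0.409). No type I (adjusted p = 0.2705), S phase (0.4695), endothelial (0.357), muscle (0.495), melanocyte (0.732; median 0.14, mean -0.80), erythroid (0.357), glycolysis (0.898; median 0.00, mean 0.01, test down), mitochondrial (0.179) or excitability gene (0.0698) was called, over all genes or over its list alone. With the replicate block, the taste bud keratins (adjusted p = 0.0105) and gland genes (0.0204) passed. With no filter on low counts 6 lists passed: type II markers (0.0287), taste bud keratins (0.04998), stem markers (0.0287), gland genes (0.0254), mitochondrial genes (0.0432) and excitability genes (0.0254). Several lists passed with 1 library left out: type II markers without Low replicate 2 (3.7e-04), MedLow replicate 1 (0.00672) or MedLow replicate 3 (0.0136), and taste bud keratins without Low replicate 1 (0.0135), MedLow replicate 3 (0.00295) or High replicate 2 (0.0383). Gland genes passed without Low replicate 1 (0.0163), MedLow replicate 3 (0.0294), High replicate 1 (0.0203) or High replicate 2 (0.0309), and excitability genes without Low replicate 2 (0.0194) or MedLow replicate 3 (0.02475). Lineage factors passed without Low replicate 2 (0.04905), mitochondrial genes without MedLow replicate 2 (0.0161) and type I markers without HiMed replicate 1 (0.00263). Among the members Krt18 (-1.06, adjusted p = 0.00715), the calcium channel Itpr3 (-0.55) and Foxa1 (-0.62) fell.

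**Figure D3:**
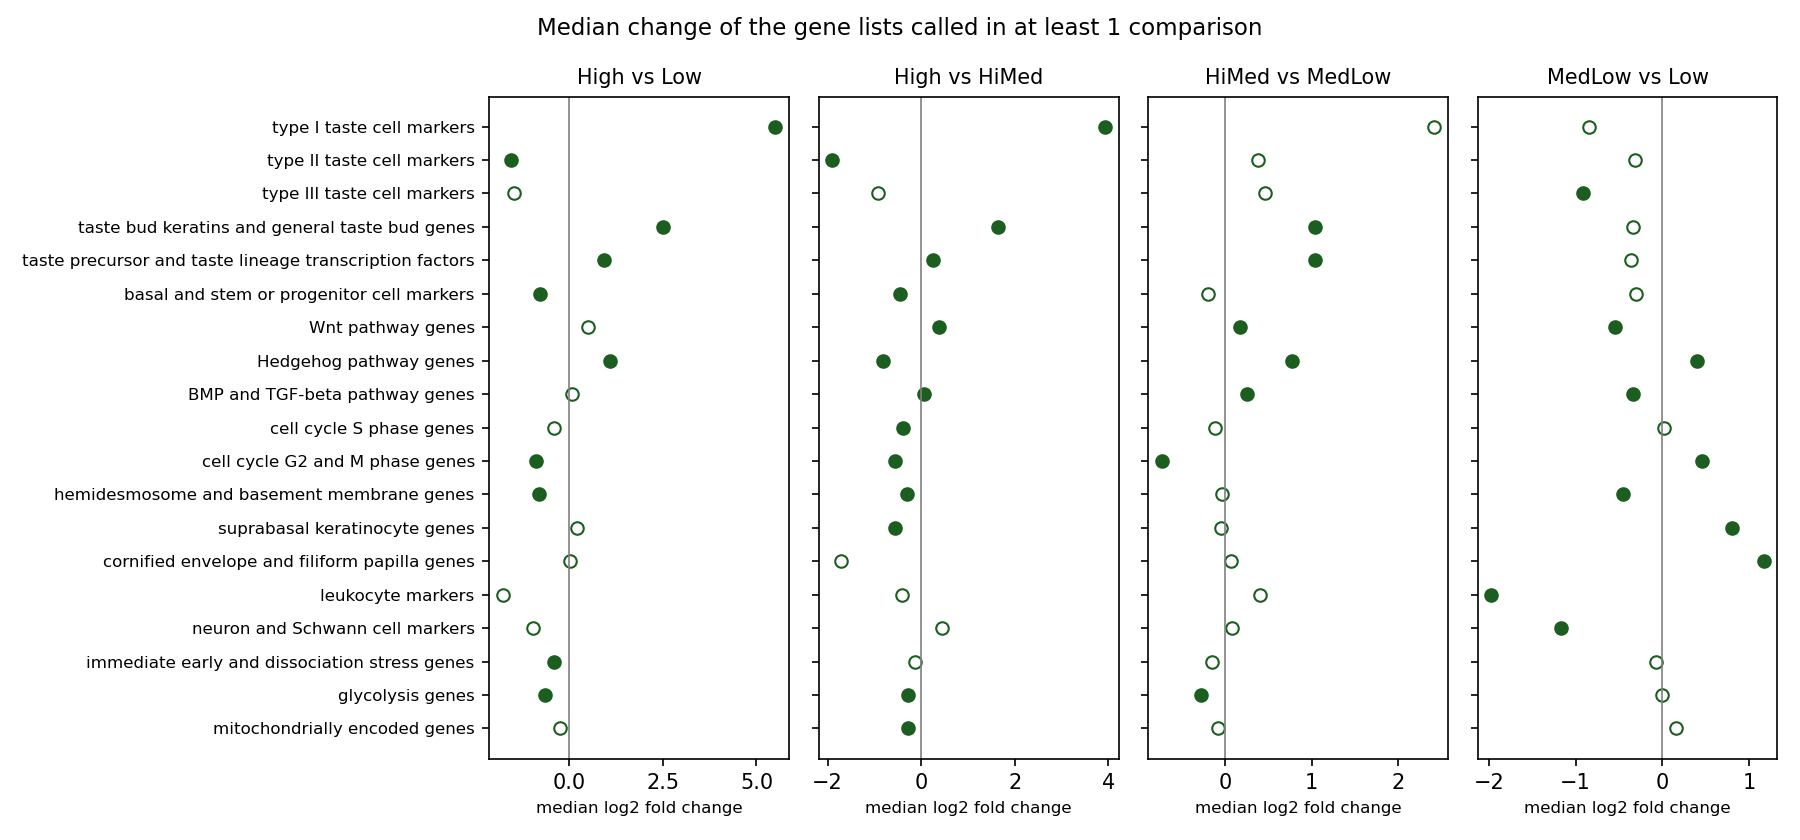
Median log2 fold change (horizontal axis) of the genes in each of the 19 lists called in at least 1 comparison (vertical axis), for the 4 comparisons. Filled points mark lists called by camera with the preset correlation. The median of the Hedgehog list rises to MedLow and HiMed and falls from HiMed to High. With an estimated correlation, only its rise from Low to MedLow is called.

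Genes higher in a middle bin than in both its neighbours were the last comparison. In HiMed, 121 genes were higher than in both neighbouring bins and 71 were lower. Among the highest were Cavin2, with 13.4 ± 0.474, 18.2 ± 4.76, 65.9 ± 12.5 and 15.97 ± 5.01 CPM from Low to High, and the angiopoietin receptor Tek, with 4.05 ± 1.21, 3.69 ± 1.44, 17.8 ± 6.31 and 6.34 ± 2.41. The drug-metabolising enzyme Fmo2 had 18.8 ± 5.85, 44.6 ± 8.78, 118 ± 14.1 and 33.9 ± 5.05 CPM, and Medag 2.69 ± 0.402, 4.90 ± 1.60, 18.5 ± 2.83 and 2.07 ± 1.07. Ptch1 also met the criterion. In MedLow, 35 genes were higher than in both neighbours and 79 lower. The tight junction gene Cldn1 had 36.1 ± 4.68, 101 ± 8.82, 53.9 ± 10.1 and 19.03 ± 1.88 CPM, thrombomodulin (Thbd) 129 ± 11.2, 280 ± 35.5, 157 ± 16.3 and 73.0 ± 11.9, and the sodium pump subunit Atp1b3 313 ± 24.4, 566 ± 11.8, 343 ± 57.3 and 123 ± 26.4. Against both neighbours these 3 genes had adjusted p of 0.00511 or less. Spata13, also counted for MedLow, had 24.2 ± 2.02 CPM there but 30.8 ± 8.06 in High, which is not a neighbour. The count for MedLow moved between 6 without MedLow replicate 1 and 53 without High replicate 3, with 12 without Low replicate 1, 16 without Low replicate 3, 13 without MedLow replicate 2, 18 without MedLow replicate 3, 22 without HiMed replicate 3 and 62 with the replicate block. The count for HiMed was 69 without MedLow replicate 2 and 75 without HiMed replicate 3.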

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

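Sox2 kept its direction and call under every alternative, with log2 fold changes of 2.39 to 2.61, 1.11 to 1.24, 0.81 to 0.92 and 0.45 to 0.49 from High against Low down to MedLow against Low. Counts of genes kept within 1.5 times of those reported except as follows, and the cause was not tested unless given. The 35 genes highest in MedLow became 65 with DESeq2, 66 with voom, 16 with TPM + 1 and 10 with TPM + 0.1. The 121 genes highest in HiMed became 78 with TPM + 1, 70 with TPM + 0.1 and 55 with TPM unfiltered. The 1127 genes of MedLow against Low became 699 with TPM + 1, 647 with TPM + 0.1, 564 with TPM unfiltered and 1806 when only their 6 libraries were fitted, and the 2377 of HiMed against MedLow became 1196 with TPM unfiltered. With the replicate block, 62 genes were highest in MedLow, and the counts of genes differing were 7352, 4188, 2828 and 1516 for the 4 comparisons. Of the gene lists, 10, 14, 7 and 10 were called, against 0, 0, 0 and 5 with an estimated correlation and 16 for MedLow against Low with no filter on low counts. The block ended the calls of the Wnt and BMP lists between HiMed and High (adjusted p = 0.0723 and 0.1004) and of Trpm5 (0.05002) and Slc1a3 (0.0866) there. It also ended those of Cldn5 (0.0540), Hbb-bs (0.0632) and Pdgfra (0.0530) between Low and High, Bst2 (0.0562) between HiMed and High, Kcnq3 (0.0556) between MedLow and HiMed, and Dcpp2 (0.0761), Sprr2a1 (0.0602) and Top2a (0.0637) between Low and MedLow. It gave calls to Krt8, Krt13, the taste bud keratins and the gland genes between Low and MedLow and to type III markers between MedLow and HiMed, and changed no other call among the genes and lists followed. Leaving out each library in turn gave 1402 to 2556 genes for HiMed against MedLow, 669 to 1335 for MedLow against Low, 69 to 133 highest in HiMed and 6 to 53 highest in MedLow. For type I markers of High against Low, adjusted p ran from 0.003315 to 0.70 (the direction reversed without HiMed replicate 1). For uncalled genes whose sign turned, the log2 ranges were -0.0165 to 0.0466 for Trp63 and -0.30 to 0.31 for Trpm5 (HiMed against MedLow), and -0.0067 to 0.16 for Mki67 and -0.50 to 0.12 for Trpm5 (MedLow against Low). Cenpf of High against HiMed turned to 0.0389 with TPM + 1. The share of higher calls moved from 48.6 to 67.8% (High against Low), 47.5 to 65.4% (High against HiMed) and 53.8 to 71.8% (HiMed against MedLow) with TPM + 1, where the median of all genes shifted by 0.19, 0.11 and 0.10, and to 55.8, 53.6 and 65.5% with library size only. Of 414 called gene comparisons followed, 66 lost the call in some alternative and 95 in some set with 1 library left out. With both HiMed replicate 1 and High replicate 1 left out, chosen after seeing the data, the 4 comparisons gave 7174, 3373, 1884 and 1371 genes. Genes below the count filter held 0.0339% of counts and were not tested in the fit reported.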

Other observations

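The gene families here, the tests on HiMed replicate 1 and those on type II markers were chosen after seeing the results, while the tests on ribosomal protein genes and the splits were fixed before. More families were tried than are reported here. Proteasome, keratin, integrin, core histone and heat shock families, for example, were called by camera in no comparison. Some genes of cholesterol synthesis and of the cytochrome P450 and glutathione S-transferase families rose from Low to MedLow, while of 22 aldehyde and alcohol dehydrogenase genes 5 rose and 1 fell (median 0.02, camera adjusted p = 0.191). Of 18 cholesterol synthesis genes 9 rose and 0 fell (median log2 fold change 0.46, camera adjusted p = 1.8e-11, and adjusted p = 0.208 with an estimated correlation), with squalene epoxidase, Sqle, going from 50.9 ± 7.87 to 83.1 ± 5.34 CPM (0.71, edgeR adjusted p = 0.00369). Of 34 cytochrome P450 genes 9 rose and 0 fell (median 0.43, camera adjusted p = 1.8e-09, and adjusted p = 0.0162 with an estimated correlation). Of 21 glutathione S-transferase genes 5 rose and 0 fell in that step (0.59, camera adjusted p = 2.7e-05, and adjusted p = 0.208 with an estimated correlation), and 8 fell from HiMed to High (-0.55, camera adjusted p = 0.00487, and adjusted p = 0.460 with an estimated correlation). These medians kept their sign under every scaling tried.

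Of 19 Serpinb genes, which encode protease inhibitors, 12 fell and 3 rose from Low to High (-1.92, camera adjusted p = 0.00435, and adjusted p = 0.402 with an estimated correlation), and 9 fell and 0 rose from HiMed to High (-0.75, camera adjusted p = 7.9e-06, and adjusted p = 0.373 with an estimated correlation). Of 15 Fgf ligand genes 4 rose and 1 fell from HiMed to High (0.82, camera adjusted p = 0.0418, and adjusted p = 0.460 with an estimated correlation), among them Fgf3 and Fgf20. Of 18 CC and CXC chemokine genes 6 fell and 1 rose in that step (-1.18, camera adjusted p = 0.0166, and adjusted p = 0.373 with an estimated correlation), Cxcl3 going from 37.4 ± 7.71 to 0.896 ± 0.530 CPM. Of 32 collagen genes 7 fell and 2 rose from Low to MedLow (-0.53, camera adjusted p = 7.6e-04, and adjusted p = 0.157 with an estimated correlation).

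Of 98 cytosolic ribosomal protein genes, 81 were lower and 4 higher in High than in Low (median -0.81). The family had a camera adjusted p of 3.75e-20, and an adjusted p of 0.387 with an estimated correlation. The share of counts of these 98 genes was 5.45 ± 0.355% in Low, 5.22 ± 0.303% in MedLow, 4.08 ± 0.163% in HiMed and 3.01 ± 0.349% in High. Between Low and MedLow 0 of the 98 were called (median -0.04). Short genes could give such a fall through length bias. Genes matched on length and level had a median of -0.3627, above the bound of -0.40. None of 1000 drawn lists fell as far as the ribosomal genes (lowest -0.60). By the rule as fixed, these values argue against length bias. The matched median lay closer to the bound than the spread of 0.11 between drawn lists, which was considered only after the value was seen. With that spread, the test cannot tell whether length gave part of the fall. The 4871 other genes as short as most ribosomal genes, not matched on level, had a median of -0.0477. Shortness alone thus did not go with a fall of that size. Reads shared with the 310 named pseudogenes do not account for the fall, since the sum over genes and these copies still changed by -0.8507. Copies without such a name were not in the sum, so reads shared with them cannot be judged. The median stayed negative at -0.73 with library size only and -0.69 on TPM, and no biological explanation was tested beyond the bin itself.

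HiMed replicate 1 stood apart from the other HiMed libraries on component 3 (51.3 against -11.7 and -17.9), with less Krt13 and more Shh. A brighter gate could do this, and its deviation correlated at 0.2129 with the change from MedLow to High, against -0.36 and 0.10 for the others, which cannot tell. Sox2 had 168 CPM in HiMed replicate 1, against 173 and 173 in the other HiMed libraries. The eGFP transcript had 255 CPM, against 224 and 259. Reporter and Sox2 RNA thus gave no sign of a brighter gate, unlike Shh and Krt13. Low complexity could also contribute, as 16.0463% of genes at 0.5 to 2 CPM in the other HiMed libraries had 0 counts there, against 2.05 and 3.22% for those libraries. This was 4.98 times the higher of these, short of the threshold of 5, and High replicate 1 had 12.1% against 4.98 and 4.02%. Among abundant genes 1.02% lay 2-fold apart, against 0.221 and 0.236%.

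Of 15 type II markers, 10 fell from HiMed to High and 5 were not called, and the list's adjusted p was 0.496 with an estimated correlation. As a hypothesis, the share of type II cells may be lower in High: deviations of the 15 markers from their bin means correlated at a mean of 0.577, above all 1000 lists matched on level (highest 0.186). That shows the markers vary together between libraries, not that cell shares set the difference between bins. Median deviations of the markers were widest outside the bins compared, from -0.71 to 0.53 in Low and from -0.87 to 0.47 in MedLow. They ran from -0.16 to 0.275 in HiMed and from -0.08 to 0.14 in High. The markers did not change by 1 common amount: Rgs21 changed by -3.23 and Itpr3 by -0.46, while Pou2f3 (-0.03) and Fxyd6 (0.49) were not called. Unequal changes do not decide on a shared factor, since the part of each marker's RNA that came from other cells was not measured. The list's median was -1.90 with TMM, -1.90 with RLE, -1.8666 with library size only and -1.34 with TPM + 1. Library size only could not decide on scaling by itself, as it moves the median of all genes by only 0.0318. The taste bud keratins and related genes had a median of 1.65 in the same comparison. A scaling factor moves all genes of a library alike, so by construction it leaves the gap between the type II markers and those genes in place. That gap is therefore no test of scaling. Whether scaling gave part of the fall of the type II markers itself cannot be told.

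Libraries were regrouped to see how often other splits give as many calls. Among 100 splits of the 12 libraries, 1, the real one, had as many genes differing among the bins, and the highest other had 5501. Splits with as many genes highest in a middle bin numbered 2 for HiMed (highest other 141) and 2 for MedLow (highest other 111), the real one included. The 5501, the 141 and the 111 all came from a split that keeps 10 of 12 libraries in place. Each comparison of 2 bins has only 10 splits, too few to say: for genes, 1 of 10 reached the real count in every comparison and the others gave 0. For gene lists with the preset correlation, other splits gave up to 7 (High against Low), 8 (High against HiMed), 9 (HiMed against MedLow) and 15 (MedLow against Low) called lists. Splits with as many lists as the real one numbered 1, 1, 7 and 3 of 10, and among the 4 that part all 3 replicate pairs, the highest other was 6, 8, 8 and 6. On those, only HiMed against MedLow had another split with as many lists, and 4 are too few to say for the rest. Since other splits called 3 to 15 lists in MedLow against Low and up to 9 elsewhere, the call of a single list is weak evidence.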
